A study of Mus musculus with 11 samples.

How the data were processed

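The series measured messenger RNA of sorted mouse cells on 11 single-colour Affymetrix arrays. The mice carried 2, 1 or no intact copies of Zbtb46, a zinc finger transcription factor gene into which gfp was inserted, and are called WT (no gfp allele), Het (1 gfp allele) and KO (2 gfp alleles). From bone marrow of each genotype 3 stages of erythroid development were sorted, named Pre MegE, Pre CFU-E and CFU-E per the labels, which gives 9 progenitor arrays with 1 array per genotype and stage. CD4+ dendritic cells (DC) were sorted from the spleen of WT and KO mice, with 1 array each. Per the labels' protocols, total RNA was labelled with biotin through the Ambion/Affymetrix WT Expression Kit.

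The deposited values are intensities on a linear scale, 1 per probe set and array, summarised with RMA per the submitters' processing notes. The RMA version and any filter or later centring are not given in the sources used here. The linear scale was taken from the values, which were all positive with array medians between 195.66 and 218.37. The log2 of each intensity was taken, and no further scaling was applied in the fits that lead the text. Of 29674 probe sets, 21780 had 1 gene symbol, 1618 had several and 6276 were not listed with a gene in the annotation used here. Genes were named only from probe sets with 1 symbol, which gave 19934 genes. For 995 genes with more than 1 probe set, the one with the highest mean over the 11 arrays was used. Probe sets of 1 gene can disagree in size, for example for Prkch (-3.152 and -2.043) and Irf1 (-1.715 and -0.792) in CFU-E against Pre MegE. Gene numbers matched the reference table for 19851 genes, and 0 symbols needed an update.

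Genes entered a fit if at or above the median of all probe sets on at least 2 of its arrays. This left 10701 genes for the 9 progenitor arrays and 11560 genes for all 11 arrays. A gene could still lie below the median in a group compared, and its fold is then best read as a lower bound. Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes, two-sided) with Benjamini-Hochberg adjustment, and a gene is called at an adjusted p under 0.05. Stages and genotypes of the progenitors were compared in 1 additive fit with 4 residual degrees of freedom, so that stages were compared within genotypes and genotypes within stages. The median residual SD was 0.0705 on the log2 scale. The difference of DC from progenitors was fitted over all 11 arrays with genotype as a block. KO was compared with WT in DC as the difference of 2 arrays, over 10554 genes at or above the median on at least 1 of them, with no replicate check. A further fit over all 11 arrays gave the DC pair the spread between the progenitor arrays, and tested whether the KO effect differed between DC and progenitors. It assumes that the lone DC arrays vary like the progenitor arrays. The labels do not say whether the stages of a genotype came from the same mice, so the p-values measure agreement between these arrays and may leave out differences between mice. The number of arrays limits the precision.

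Before the data were examined, 25 gene lists were fixed: erythroid program, heme synthesis, iron handling, megakaryocyte and platelet, stem and multipotent progenitor, granulocyte and monocyte progenitor, mast cell and basophil, G2 and M phase, DNA replication, ribosome biogenesis, cholesterol synthesis, type I interferon response, immediate early and heat shock, classical DC core, CD4+ DC subset, CD8+ DC subset, plasmacytoid DC, DC maturation, MHC class II presentation, monocyte and macrophage, cytokine receptors of myeloid growth factors, B cell, T cell, NK cell and sex-linked genes. Some lists share genes, such as Csf1r and Lyz2 in the granulocyte and the monocyte lists and H2-Aa and Cd74 in the MHC class II and classical DC core lists. Lists that pass together are thus not always separate results. Each list was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with a correlation estimated from the residuals. For the DC pair, the median of a list is given as its percentile among 10000 random lists of the same size matched on mean expression. The genes named were also fixed by rule: Zbtb46 first, then in each tested comparison the 12 largest rises and 12 largest falls (8 and 8 for DC against progenitors) among called genes with the same sign in every block, leaving out symbols of predicted genes. Where fewer than 10 genes were called, all were named and then the 8 largest mean differences each way with the same sign in every block. For the DC pair, the rule took the 12 largest differences each way. Up to 4 called members were named from a list whose camera test passed, and otherwise at most 2 members.

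On simulated data with known differences over 10701 genes, the KO against WT comparison of the progenitors called 28.4% of genes changed by 0.25, 83.6% of those changed by 0.5 and 100% of those changed by 1 on the log2 scale, and 3.42% of its calls were false. For CFU-E against Pre MegE the shares called were 46.3%, 85.1% and 95.5% over 10701 genes, with 6.21% false calls. For the DC pair given the progenitors' spread, over 11560 genes, they were 2.99%, 38.8% and 86.4%, with 7.61% false calls. In each of these comparisons 100% of the called genes had the right direction. The simulated DC arrays were given the progenitors' spread, so the DC shares hold only if real DC arrays vary alike. A list of 20 genes shifted by 0.25 in KO against WT over 10701 genes gave an adjusted p of 1.25e-36, and 0 of 100 random lists passed. The simulated noise was drawn independently for each gene, so this does not show how the preset correlation serves lists of genes that vary together. It was also drawn independently for each array. The share of false calls for KO against WT therefore leaves out differences between mice that all arrays of a genotype share.

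The alternatives tried were no filter or one at percentile 65, quantile normalization again, centring each array on its median, the mean of a gene's probe sets, limma with trend and robust settings, array weights, other sets of arrays, no genotype block, an estimated correlation for the lists, other fold thresholds for the DC pair, and leaving out each array in turn. Array weights were estimated gene by gene because the first method tried stopped before it converged, a change made after the data were seen. Alternatives that left out the WT arrays, 1 stage or the sex-linked list were also added after the data were seen. Probe sets with several symbols or none were left out of the gene tests and are summarised separately.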

Results

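Zbtb46, a zinc finger transcription factor gene known for its expression in classical DC and their precursors, was disrupted in these mice by an inserted gfp reporter. RNA was measured in 3 sorted populations of bone marrow and in splenic CD4+ DC. Pre MegE cells, sorted as lineage-negative cells with CD117 and CD150 and without CD105, CD41 or the Fc gamma receptor, can give rise to megakaryocytes and red cells. Pre CFU-E cells differed in their gate by low CD105, and CFU-E cells, the erythroid colony-forming stage, by high CD105 and no CD150. CD4+ DC were B220-negative cells with CD11c, MHC class II, CD172, CD11b and CD4 and without CD8. Each of the 3 stages was measured in WT, Het and KO mice and the DC in WT and KO mice, with 1 array per genotype and cell type, 11 arrays in all. The median intensity per array was between 198.63 and 218.37 in progenitors and was 195.66 and 199.21 in WT and KO DC. The upper quartile was 967.58 to 1009.3 in progenitors, but 641.43 in WT DC and 604.76 in KO DC.

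Zbtb46 itself was read first in every array, as the targeted gene. In CD4+ DC its log2 intensity was 9.67 in WT and 8.02 in KO, a 3.14-fold lower level. In WT progenitors it was 7.52 at Pre MegE, 8.14 at Pre CFU-E and 8.87 at CFU-E. Het progenitors had 7.67, 8.30 and 8.62 at the same stages, and KO progenitors 7.71, 7.70 and 7.50. The KO minus WT difference was thus 0.19 at Pre MegE, -0.44 at Pre CFU-E and -1.37 at CFU-E, where KO was 2.58-fold lower. At Pre MegE every genotype lay below its array's median (7.76 in WT, 7.77 in Het and 7.75 in KO), so a loss in KO might not show there. KO at CFU-E also lay below its array's median (7.63). Averaged over stages, Zbtb46 was not called between KO and WT (log2 difference -0.54, SE 0.226, limma adjusted p = 0.847), between Het and WT (0.02, adjusted p = 0.999) or between KO and Het (-0.56, adjusted p = 1). That fit takes the genotype difference to be alike at every stage, so it cannot call a difference confined to 1 stage. Where the array's Zbtb46 probes lie relative to the insertion is not given in the sources used here, so a remaining signal in KO does not tell whether an intact transcript was made.

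**Figure D1:**
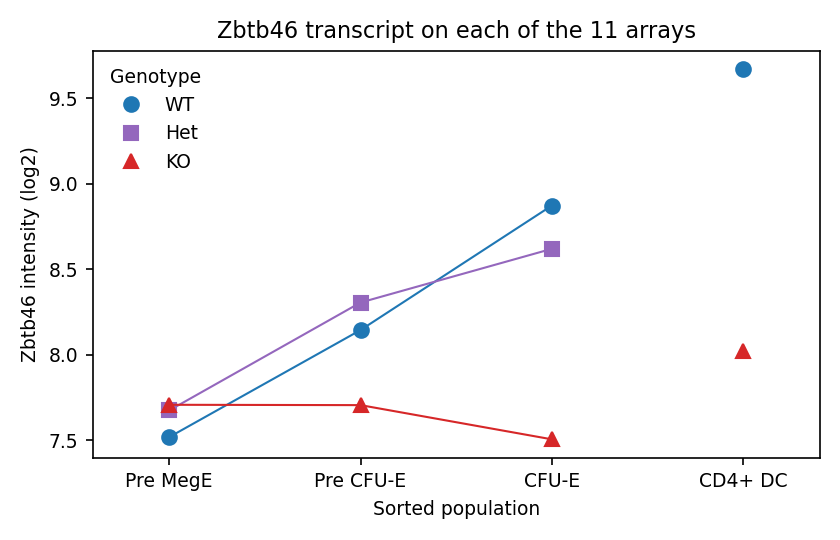
Log2 intensity of Zbtb46 (y axis) in each sorted population (x axis) for WT (blue circles), Het (purple squares) and KO (red triangles), 1 array per point, with lines joining the progenitor stages of a genotype. WT rises from 7.52 to 8.87 over the 3 stages while KO lies at 7.71, 7.70 and 7.50, and in CD4+ DC the KO array (8.02) lies below the WT array (9.67).

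The step from Pre MegE to Pre CFU-E asks what changes as cells commit to the erythroid lineage. Genes of stem cells, megakaryocytes and granulocytes fell as lists. Erythroid, heme synthesis and iron handling genes rose as lists with the preset correlation, and these 3 calls were lost with an estimated one (adjusted p = 0.054, 0.128 and 0.122). Rhd, a subunit of the Rh blood group complex, rose by 3.01 log2 (SE 0.0835, 8.06-fold, adjusted p = 1.45e-08, n = 3 arrays per stage, higher in 3 of 3 genotypes). Adgrl4, an adhesion receptor, fell by 3.22 (SE 0.0637, 9.34-fold, adjusted p = 2.75e-09). Cd34, the surface marker of early blood progenitors, fell by 3.12 and Meis1, a stem cell transcription factor, by 3.01. Of 10701 genes, 7099 changed at a limma adjusted p under 0.05, 3965 higher and 3134 lower, and 648 of them by at least 2-fold (182 higher, 466 lower). With each array centred on its median the split was 5045 higher and 2522 lower, and the median difference of all genes went from 0.038 to 0.12.

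Besides Rhd, the largest rises from Pre MegE to Pre CFU-E were Tlcd4 (2.96), Mboat2 (2.95), Slc26a1 (2.88), Cldn13 (2.86), the copper transporter Atp7b (2.85), the sphingosine kinase Sphk1 (2.83), the red cell pyruvate kinase Pklr (2.56), Camsap2 (2.50), Nxpe2 (2.48), Asb17 (2.45) and the amino acid transporter Slc38a5 (2.38). The other large falls were Cd180 (-3.11), Stat4 (-3.06), the platelet kinase substrate Plek (-3.03), Ctla2a (-2.95), the vesicular monoamine transporter Slc18a2 (-2.93), Clec4e (-2.88), Ctla2b (-2.85), Cd93 (-2.77) and the thromboxane synthase Tbxas1 (-2.76). All had the same direction in 3 of 3 genotypes.

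Of 28 measured erythroid genes, 21 rose and 5 fell at this step (21 and 6 adjusted over the list alone), with a list median of 0.43 (camera adjusted p = 0.00021, adjusted p = 0.054 with an estimated correlation). Rhag, the partner of Rhd, rose by 1.66. In heme synthesis 8 of 12 genes rose and 3 fell, with Cpox at 1.78, Abcb6 at 1.22 and the ferrochelatase Fech at 0.86, and the list passed (adjusted p = 0.0377, adjusted p = 0.128 with an estimated correlation). In iron handling 8 of 12 rose and 2 fell (adjusted p = 0.0287, adjusted p = 0.122 with an estimated correlation), among them the iron exporter Slc40a1 (1.24) and the transferrin receptor Tfrc (1.11). All 16 measured megakaryocyte genes fell, with a median of -1.61 (adjusted p = 1.26e-09), including Plek, the integrin Itga2b (-2.21), Mef2c (-1.93) and Gp9 (-1.76). Among stem and multipotent progenitor genes 18 of 19 fell, with a median of -1.57 (adjusted p = 3.06e-10), including Cd34, Meis1, Angpt1 (-2.57) and Mycn (-2.54). All 17 granulocyte and monocyte genes fell, with a median of -0.90 (adjusted p = 1.42e-08), including Spi1 (-1.41), Csf3r (-1.13), Lyz2 (-1.08) and Mpo (-0.98).

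In the G2 and M phase list 22 of 23 genes rose (median 0.62, adjusted p = 1.65e-07, adjusted p = 0.0602 with an estimated correlation), with the kinases Aurka at 0.97 and Plk1 at 0.84. In DNA replication 22 of 25 rose (median 0.41, adjusted p = 4.43e-06, adjusted p = 0.16 with an estimated correlation), led by cyclin E1, Ccne1, at 2.05 and Rrm2 at 1.20. In ribosome biogenesis 22 of 23 rose (median 0.48, adjusted p = 2.53e-06, adjusted p = 0.0541 with an estimated correlation), with Nip7 at 0.97 and Rrp9 at 0.95. In cholesterol synthesis 16 of 18 rose (median 0.45, adjusted p = 0.000739, adjusted p = 0.121 with an estimated correlation), with Idi1 at 0.81 and Msmo1 at 0.72. Immediate early and heat shock genes went the other way, with 19 of 20 falling and 1 rising (median -1.05, adjusted p = 8.36e-10), among them Nr4a1 (-2.45), Btg2 (-1.92) and Klf6 (-1.81). All 6 mast cell genes fell (median -1.72, adjusted p = 0.000172, adjusted p = 0.0856 with an estimated correlation), including Cpa3 (-2.23) and Hdc (-1.90).

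In 5 smaller lists of myeloid and lymphoid genes a shift to lower values passed with the preset correlation and was lost with an estimated one. Cytokine receptors had 7 of 8 lower and 1 higher (median -0.71, adjusted p = 0.00523, adjusted p = 0.0858 with an estimated correlation), with the shared receptor chain Csf2rb at -2.21. B cell genes had 5 of 6 lower (median -0.62, adjusted p = 0.00359, adjusted p = 0.0856 with an estimated correlation), with Cd79b at -1.30. MHC class II genes had 5 of 6 lower (median -0.84, adjusted p = 0.00838, adjusted p = 0.0978 with an estimated correlation), with H2-Ob at -2.66. DC maturation genes had 6 of 11 lower (median -0.24, adjusted p = 0.00755, adjusted p = 0.122 with an estimated correlation), with Il15 at -1.79. The CD4+ DC subset list had 4 of 6 lower and 1 higher (median -0.60, adjusted p = 0.0377, adjusted p = 0.128 with an estimated correlation), with Esam at -1.27 and Sirpa at -1.14. The lists for interferon response (0.105), classical DC core (0.0796), CD8+ DC subset (0.384), plasmacytoid DC (0.234), monocyte and macrophage (0.0653), T cell (0.227) and sex-linked genes (0.12) did not pass, with the adjusted p in brackets. Of the NK cell list 1 gene was measured, Nkg7 (-1.96), so the list was not tested. Over all 24 lists tested, 17 passed (7 up, 10 down), and 4 held with an estimated correlation, those of megakaryocyte, stem, granulocyte and immediate early genes, all lower. Without the KO CFU-E array heme synthesis no longer passed (adjusted p = 0.0551), and monocyte and macrophage genes passed without Het Pre CFU-E (0.0499), WT Pre CFU-E (0.0358) or WT Pre MegE (0.0498). Without the filter, which adds genes of low signal, monocyte and macrophage (0.00213), classical DC core (0.00475) and interferon response genes (0.00191) passed, all lower. After quantile normalization iron handling (0.0613) and the CD4+ DC subset (0.0849) did not.

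From Pre CFU-E to CFU-E, the later step of erythroid maturation, genes of heme synthesis and of the erythroid list rose, and stem cell genes fell as a list, a shift lost with an estimated correlation (adjusted p = 5.04e-09, adjusted p = 0.058 with an estimated correlation). Pkhd1l1 rose by 3.19 (SE 0.0839, 9.11-fold, adjusted p = 2.45e-08, n = 3 arrays per stage, higher in 3 of 3 genotypes). Ifitm1, an interferon-induced membrane protein, fell by 4.01 (SE 0.0569, 16.1-fold, adjusted p = 1.26e-09). Slamf1, which encodes the CD150 used in the gate, fell by 3.20, so its fall follows from the sort. There were 4712 genes changed, 2004 higher and 2708 lower, of which 316 changed by at least 2-fold (79 higher, 237 lower). The balance depended on scaling, with 2499 higher and 2309 lower after centring each array on its median and 2307 and 2475 after quantile normalization. Without the WT Pre CFU-E array 1322 were higher and 2120 lower.

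The other large rises at this step were the lipid phosphatase Plpp1 (2.63), the fatty acid desaturases Scd1 (2.40) and Fads3 (2.31), Trim10 (2.24), Pdia2 (2.22), Tlcd4 (2.12), Sec14l2 (2.10), the membrane skeleton protein Epb42 (2.03), St3gal6 (2.01), Btnl10 (2.01) and Sh2d4a (1.98). The other large falls were Ctla2a (-3.03), the melanocortin receptor Mc5r (-2.97), Muc13 (-2.81), St8sia6 (-2.73), Prkch (-2.67), the thrombin receptor F2r (-2.65), Pdcd1 (-2.53), Rgs1 (-2.30), Dock2 (-2.25) and Rab37 (-2.14). All had the same direction in 3 of 3 genotypes.

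All 12 heme synthesis genes rose (median 0.66, adjusted p = 7.98e-09), among them Uros (1.34), Ppox (0.98), Abcb6 (0.98) and Tmem14c (0.90). Of 28 erythroid genes 18 rose and 2 fell (19 and 2 adjusted over the list alone), with a median of 0.37 (adjusted p = 1.16e-08), led by Trim10, Epb42, the beta spectrin Sptb (1.86) and Cldn13 (1.44). In iron handling 8 of 12 rose (median 0.23, adjusted p = 0.000996, adjusted p = 0.0776 with an estimated correlation), with Tfrc at 0.74 and Slc40a1 at 0.48. DNA replication genes rose in 23 of 25 (median 0.27, adjusted p = 5.04e-09, adjusted p = 0.191 with an estimated correlation), with Ccne1 at 0.98 and Rrm2 at 0.79. G2 and M phase genes rose in 14 of 23 (15 adjusted over the list alone, median 0.24, adjusted p = 5.13e-05, adjusted p = 0.126 with an estimated correlation), with Birc5 at 0.41. Ribosome biogenesis did not shift (adjusted p = 0.809), with 1 gene higher and 4 lower (0 and 1 adjusted over the list alone) and Myc at -0.44. Cholesterol synthesis had 5 of 18 genes higher and did not pass (adjusted p = 0.0571).

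Among stem and multipotent progenitor genes 16 of 19 fell (median -0.61, adjusted p = 5.04e-09, adjusted p = 0.058 with an estimated correlation), including Angpt1 (-2.03), Myct1 (-1.89) and Meis1 (-1.82). Immediate early genes fell in 18 of 20 (median -0.73, adjusted p = 6.66e-09), including Klf6 (-1.50), Atf3 (-1.39) and Egr1 (-1.38). Megakaryocyte genes had 10 of 16 lower and 1 higher (11 and 1 adjusted over the list alone, median -0.54, adjusted p = 0.000547, adjusted p = 0.0743 with an estimated correlation), with F2r, Mef2c (-1.60) and Fli1 (-1.35). In the mast cell list 2 of 6 fell, Hdc (-1.78) and Cpa3 (-1.46), and its shift was lost with an estimated correlation (adjusted p = 0.0296, adjusted p = 0.265 with an estimated correlation). The granulocyte list, with 6 of 17 lower and 1 higher, did not pass at this step (adjusted p = 0.227). None of the DC, MHC class II, monocyte, cytokine receptor, interferon, lymphoid or sex-linked lists passed (adjusted p from 0.0571 for MHC class II to 0.809), although H2-Oa (-1.73), Dpp4 (-1.28), Wdfy4 (-0.93) and Nkg7 (-1.42) fell as single genes. Of 24 lists tested, 9 passed (5 up, 4 down), and 3 held with an estimated correlation, those of erythroid, heme synthesis and immediate early genes. In 3 lists, none of which passed, the median, the mean and the test differed in sign. The mast cell call was lost without KO CFU-E (adjusted p = 0.0586). MHC class II genes passed without any 1 of Het CFU-E, Het Pre MegE, KO CFU-E, KO Pre CFU-E and KO Pre MegE (0.0354 to 0.049) and cholesterol synthesis genes without Het Pre CFU-E (0.0288) or WT CFU-E (0.0347) or after quantile normalization (0.0459). Without the filter granulocyte genes passed, lower (0.0256), and mast cell genes did not (0.11).

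Over the whole span from Pre MegE to CFU-E, Tlcd4 rose by 5.08 (SE 0.139, 33.8-fold, adjusted p = 1.93e-09), the claudin Cldn13 by 4.30 (19.7-fold) and Rhd by 4.26 (19.2-fold). Tlcd4 averaged 7.32 in Pre MegE, below the medians of those arrays, so its fold is best read as a lower bound. Ctla2a, a protease inhibitor, fell by 5.98 (SE 0.127, 63.3-fold, adjusted p = 4.78e-10) and Meis1 by 4.83 (28.4-fold), each in 3 of 3 genotypes. There were 8202 genes changed, 4443 higher and 3759 lower, and 1601 of them changed by at least 2-fold (559 higher, 1042 lower). A test for any difference among the 3 stages called 8389 genes. With each array centred on its median the split was 5696 higher and 3085 lower and the median difference of all genes moved from 0.050 to 0.17.

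The remaining large rises over the span were Mboat2 (3.95), Plpp1 (3.72), Paqr9 (3.71), Atp7b (3.66), Sh2d4a (3.62), Pkhd1l1 (3.61), Camsap2 (3.59), Sphk1 (3.50) and the aldehyde dehydrogenase Aldh1a7 (3.49). The remaining large falls were the G protein regulator Rgs1 (-4.83), Slamf1 (-4.77), the angiopoietin Angpt1 (-4.60), Ifitm1 (-4.59), F2r (-4.39), Myct1 (-4.26), Ctla2b (-4.25), Mc5r (-4.17), Slc18a2 (-4.03) and St8sia6 (-4.02). Zbtb46 was 0.70 higher in CFU-E than in Pre MegE (SE 0.226, adjusted p = 0.0183), with differences from -0.20 in KO to 1.35 in WT, so the call does not describe the KO cells. It was lost without the Het CFU-E array (0.63, adjusted p = 0.0751), the Het Pre MegE array (0.58, adjusted p = 0.0861), the WT CFU-E array (0.42, adjusted p = 0.0973), the WT Pre MegE array (0.48, adjusted p = 0.0962) or all WT arrays (0.37, adjusted p = 0.181), and over all alternatives the adjusted p ranged from 0.00021 to 0.181. For the single steps Zbtb46 was not called (0.42, adjusted p = 0.132 and 0.28, adjusted p = 0.348). The first passed without the KO Pre MegE array (0.75, adjusted p = 0.00585) or the KO CFU-E array (0.42, adjusted p = 0.0176) and with only the 2 stages compared (adjusted p = 0.0176), and ranged up to 0.49 over its alternatives, and the second passed without the KO CFU-E array (0.63, adjusted p = 0.00922) and with array weights (0.57, adjusted p = 0.00914), and ranged from 0.00914 to 0.989.

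Of the fixed lists, erythroid genes had 24 of 28 higher and 3 lower (median 0.81, adjusted p = 3.9e-06) and heme synthesis 11 of 12 higher (median 1.17, adjusted p = 7.49e-05), with Cpox at 2.35, Abcb6 at 2.20, Uros at 1.96 and Tmem14c at 1.70. Iron handling had 9 of 12 higher and 2 lower (median 0.53, adjusted p = 0.0119, adjusted p = 0.0882 with an estimated correlation), with Tfrc at 1.85 and Slc40a1 at 1.71. All 25 DNA replication genes rose (median 0.79, adjusted p = 2.18e-07, adjusted p = 0.141 with an estimated correlation), with Ccne1 at 3.03 and Rrm2 at 1.99. So did all 23 G2 and M phase genes (median 0.84, adjusted p = 3.63e-07, adjusted p = 0.0655 with an estimated correlation), with Plk1 at 1.12 and Bub1b at 1.08. Ribosome biogenesis had 21 of 23 higher and 1 lower (median 0.47, adjusted p = 0.000207, adjusted p = 0.0862 with an estimated correlation), with Nip7 at 1.10. Cholesterol synthesis had 16 of 18 higher (median 0.54, adjusted p = 0.00134, adjusted p = 0.119 with an estimated correlation), with Pmvk at 1.31 and Sqle at 1.17.

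Stem and multipotent progenitor genes fell in 18 of 19 (median -2.88, adjusted p = 3.73e-09), and megakaryocyte genes in 16 of 16 (median -2.07, adjusted p = 8.62e-08), with Plek at -3.66, Mef2c at -3.53 and Fli1 at -3.06. Immediate early genes fell in 19 of 20 (median -2.10, adjusted p = 7.13e-09), with Klf6 at -3.30 and Zfp36 at -3.05, and granulocyte genes in 17 of 17 (median -0.98, adjusted p = 8.96e-07), with Spi1 at -2.27. Mast cell genes fell in 6 of 6 (median -1.95, adjusted p = 0.000673, adjusted p = 0.0882 with an estimated correlation), with Cpa3 at -3.69 and Hdc at -3.68. Cytokine receptors had 7 of 8 lower (median -0.92, adjusted p = 0.00948, adjusted p = 0.0882 with an estimated correlation), with Csf2rb at -2.37, while the erythropoietin receptor Epor rose by 1.20. MHC class II genes had 5 of 6 lower (adjusted p = 0.00843, adjusted p = 0.0882 with an estimated correlation), with H2-Ob at -3.63. B cell genes had 5 of 6 lower (adjusted p = 0.0101, adjusted p = 0.0882 with an estimated correlation), with Cd79b at -1.46. Classical DC core genes had 7 of 11 lower and 1 higher (adjusted p = 0.0293, adjusted p = 0.141 with an estimated correlation) and DC maturation genes 6 of 11 lower and 1 higher (adjusted p = 0.0293, adjusted p = 0.16 with an estimated correlation). Counts adjusted over the list alone were the same for every list over this span. The lists of interferon response, CD4+ DC subset, CD8+ DC subset, plasmacytoid DC, monocyte and macrophage, T cell and sex-linked genes did not pass (adjusted p from 0.0645 to 0.604), though Lat (-3.01) and Nkg7 (-3.38) fell as single genes. Of 24 lists tested, 17 passed (7 up, 10 down), and 6 held with an estimated correlation, those of erythroid and heme synthesis genes, higher, and of stem, megakaryocyte, granulocyte and immediate early genes, lower. After quantile normalization the classical DC core (0.0865) and DC maturation lists (0.104) did not pass. Without the filter CD4+ DC subset (0.00211), monocyte and macrophage (0.00528) and interferon response genes (0.00208) passed, all lower.

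**Figure D2:**
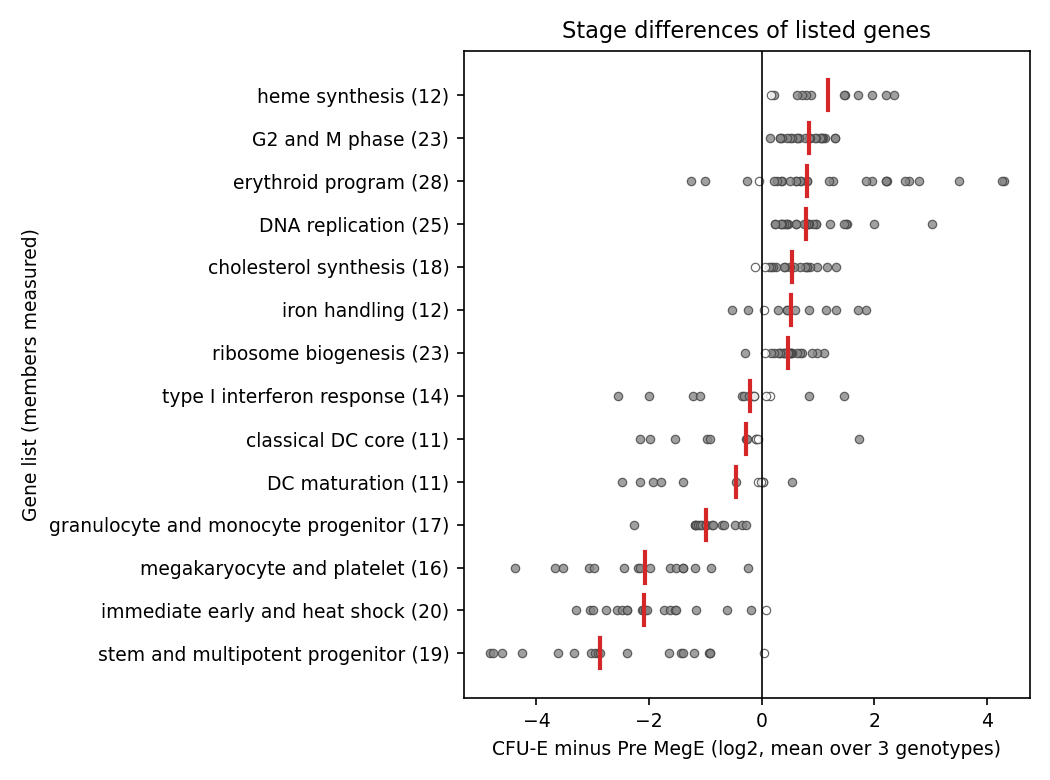
Log2 difference CFU-E minus Pre MegE (mean over 3 genotypes) of each measured member of the 14 fixed lists with at least 10 measured members, filled where the adjusted p is under 0.05 and open otherwise, with a red bar at the list median. Heme synthesis (median 1.17) and erythroid genes (0.81) lie above 0, and stem (-2.88), immediate early (-2.10) and megakaryocyte genes (-2.07) below.

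Loss of Zbtb46 in the progenitors was asked about by comparing KO with WT within each stage. No erythroid gene was called, while the granulocyte list and the eosinophil granule genes Epx and Prg2 were lower in KO. Elane, neutrophil elastase, fell by 0.43 (SE 0.0477, 1.35-fold, adjusted p = 0.0136), from a mean log2 intensity of 11.72 to 11.29, and was lower at 3 of 3 stages. Epx, eosinophil peroxidase, fell by 0.85 (SE 0.114, 1.80-fold, adjusted p = 0.0344) and Prg2, the eosinophil major basic protein, by 0.60 (adjusted p = 0.0191). The samples also differed in sex-linked genes. Xist, expressed from the inactive X chromosome, was at 11.5 to 12.3 in the 3 WT arrays and at 5.86 to 6.38 in the 6 Het and KO arrays, and the Y-linked Uty at 9.40 to 9.79 in WT and 9.81 to 10.3 in Het and KO, so that WT samples held both and sex went with genotype.

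In all, 15 of 10701 genes were called between KO and WT, 2 higher and 13 lower, of which 1, Xist, differed by at least 2-fold. The 2 higher genes were Uty (0.39, adjusted p = 0.0191) and the small nucleolar RNA Snord14e (0.32, adjusted p = 0.0484). Xist fell by 5.92 (adjusted p = 8.26e-07), to levels below the array medians, so the size of its fall is best read as a lower bound. The other lower genes were the MHC class I gene H2-Q5 (-0.83, adjusted p = 0.0114), Adgrg7 (-0.55, adjusted p = 0.0114), Igsf6 (-0.53), the granulocyte surface marker Ly6g (-0.44), the ficolin Fcnb (-0.43), the granule peptidoglycan receptor Pglyrp1 (-0.42), the myeloid lectin Clec12a (-0.42) and Ms4a3 (-0.39). BC018473 (-0.43, adjusted p = 0.0136) also passed and lies outside the naming rule. All 15 had the same direction at 3 of 3 stages.

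All 17 measured granulocyte and monocyte genes lay below 0 in KO, with a median of -0.23 and stage medians from -0.28 to -0.19. The list fell (adjusted p = 3.3e-24, adjusted p = 0.0212 with an estimated correlation), with 2 members called over all genes, Elane and Ms4a3, and 14 adjusted over the list alone. Monocyte and macrophage genes were also lower as a list (5 measured, median -0.21, adjusted p = 0.000103, adjusted p = 0.126 with an estimated correlation, 0 called and 3 adjusted over the list alone), but without the filter their median was -0.02 and the call was lost (adjusted p = 0.0925). The same direction held for immediate early genes (median -0.09, adjusted p = 4.66e-05, adjusted p = 0.126 with an estimated correlation, 0 called), mast cell genes (median -0.09, adjusted p = 0.00338, adjusted p = 0.254 with an estimated correlation, 1 adjusted over the list alone) and interferon response genes (median -0.09, adjusted p = 0.00338, adjusted p = 0.307 with an estimated correlation, 0 called). In erythroid genes 0 of 28 were called by limma (median 0.04, adjusted p = 0.0631), with Rhag at -0.20 and Sptb at 0.13, and among heme synthesis genes Urod was at 0.13. The other lists did not pass (adjusted p from 0.214 to 0.876), among them those of classical DC core, CD4+ DC subset and G2 and M phase genes. Sex-linked genes had a median of 0.30 and a mean of -1.23, since Xist was far lower and the others higher, and it was 1 of 3 lists, none of which passed, whose median, mean and test differed in sign. The mast cell call was lost without KO CFU-E (adjusted p = 0.0735), WT CFU-E (0.18) or WT Pre MegE (0.0591), and the interferon call without KO CFU-E (0.158) or WT CFU-E (0.18). Erythroid genes passed without Het Pre CFU-E (median 0.04, 0.0499) or Het Pre MegE (0.0262) or after quantile normalization (0.0238), and DNA replication genes without KO CFU-E (median 0.05, 0.0332).

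The number of genes called rested on few arrays. It was 1 without the KO Pre MegE or the WT Pre CFU-E array, 2 without WT CFU-E, 6 without WT Pre MegE, 7 without KO Pre CFU-E, 8 without Het CFU-E or Het Pre MegE and 26 without Het Pre CFU-E. Xist passed in 9 of these 9 fits and H2-Q5 in 7, Elane in 4 (-0.45 to -0.41), Epx in 2 (-0.99 to -0.68) and Pglyrp1 in 1, all with their direction kept. Without the list of sex-linked genes 11 genes were called, without the filter 7 and with array weights 46.

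**Figure D3:**
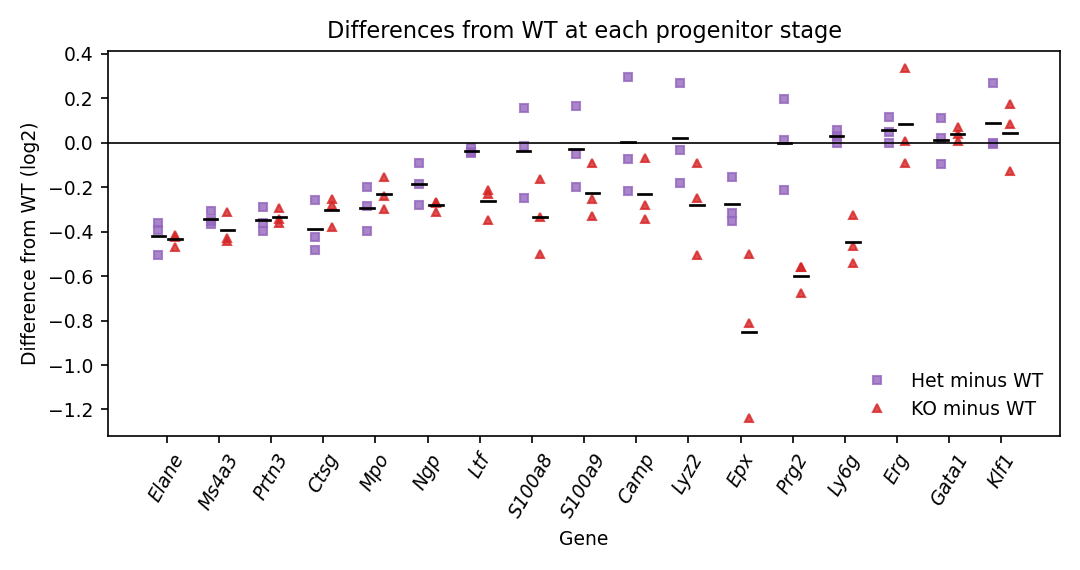
Log2 difference from WT (y axis) of granulocyte genes and of Erg, Gata1 and Klf1 (x axis) at each of the 3 progenitor stages, for Het (squares) and KO (triangles), with a black bar at the mean of the 3 stages. The genes shown were chosen after the values were seen. Elane lies at -0.42 in Het and -0.43 in KO, and Epx at -0.27 in Het and -0.85 in KO.

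With 1 gfp allele the same direction was seen for part of these genes. Elane fell by 0.42 in Het against WT (SE 0.0477, adjusted p = 0.0366, lower at 3 of 3 stages) and Adgrg7 by 0.43 (adjusted p = 0.0495). Without the sex-linked list neither was called (adjusted p = 0.0989 for both), though the differences stayed at -0.42 and -0.43 and only the adjustment over fewer called genes moved, with ranges over the alternatives of 0.00431 to 0.573 for Elane and 0.00354 to 0.602 for Adgrg7. Uty rose by 0.43 (adjusted p = 0.0366) and Xist fell by 5.74 (adjusted p = 1.1e-06). These were the 4 genes called, 1 higher and 3 lower. The largest further differences with 1 sign at all stages were, as values, Kdm5d (0.40), Sp140 (0.35), Pde7b (0.34), Snord15a (0.34), Abca1 (0.33), Mir142 (0.32), Olfr248 (0.31), H2-Q5 (-0.60, adjusted p = 0.0849), the interferon regulator Irf1 (-0.59), Ly96 (-0.54), Zfp931 (-0.41) and Igsf6 (-0.40). The Irf1 value rests on 1 of 2 probe sets that disagree (-0.685 and -0.105 in KO against WT), and their mean gave -0.32 in Het.

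In Het, granulocyte genes were lower as a list (median -0.13, adjusted p = 1.09e-11, adjusted p = 0.0851 with an estimated correlation), with 1 called and 6 adjusted over the list alone. Interferon response (median -0.09, adjusted p = 0.0129, adjusted p = 0.406 with an estimated correlation) and immediate early genes (median -0.04, adjusted p = 0.0259, adjusted p = 0.406 with an estimated correlation) were also lower, with 0 genes called in either. The other lists had adjusted p from 0.0983 to 0.919, including sex-linked genes (median 0.32, mean -1.17). In 7 lists, none of which passed, the median, the mean and the test differed in sign. The interferon call was lost without Het CFU-E (0.0575), Het Pre CFU-E (0.149) or WT CFU-E (0.299) and the immediate early call without Het CFU-E (0.0991), Het Pre CFU-E (0.526) or WT Pre CFU-E (0.3). Mast cell genes passed without WT Pre CFU-E (median -0.11, 0.0215), without the filter (0.0309) or after quantile normalization (0.0319). The count of 4 became 1 without the Het Pre MegE, Het Pre CFU-E, Het CFU-E, KO Pre MegE, KO Pre CFU-E, WT Pre CFU-E or WT CFU-E array, 2 without WT Pre MegE and 5 without KO CFU-E. The differences of KO and Het from WT correlated across 10701 genes at 0.789, where unchanged groups sharing the same WT arrays gave a mean of 0.49955 (0.470 to 0.527 in 100 simulated sets). Their covariance was 0.00705 against 0.00258 simulated, and without the sex-linked genes 0.00384 with a correlation of 0.671. Genes are not independent replicates, and part of the excess may come from the shared WT arrays. The 2 comparisons shared 1 higher call, Uty, and 3 lower calls, Xist, Elane and Adgrg7.

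KO against Het, which share their sex by the sex-linked genes, asks for an effect of the second gfp allele. By the naming rule the largest negative values, none of them called, were those of the eosinophil granule genes Prg2 at -0.60 (SE 0.0719, adjusted p = 0.0973), Epx at -0.58 and Ear6 at -0.55, followed by Ly6g (-0.47, adjusted p = 0.0973), Prg3 (-0.37), Alox15 (-0.35), Cpd (-0.34) and Olfm4 (-0.32), each lower at 3 of 3 stages. The largest positive values were Dntt (0.37), Scd1 (0.30), Igll1 (0.28), Pdcd1 (0.28), Susd2 (0.26), Snord38a (0.25), Cldn20 (0.23) and Tespa1 (0.23). limma called 0 of 10701 genes, with 255 at an unadjusted p under 0.05. Array weights gave 2, and leaving out the Het Pre CFU-E array gave 1.

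Granulocyte genes were lower in KO than in Het as a list (median -0.05, adjusted p = 0.000328, adjusted p = 0.504 with an estimated correlation, 1 adjusted over the list alone), and so were monocyte and macrophage genes (median -0.05, adjusted p = 0.0433, adjusted p = 0.511 with an estimated correlation). DNA replication genes were higher (median 0.03, adjusted p = 0.0248, adjusted p = 0.62 with an estimated correlation), with 0 genes called. The granulocyte call was lost without the KO Pre CFU-E array (adjusted p = 0.0698). The replication call was lost without Het Pre CFU-E (0.237), Het Pre MegE (0.566), KO Pre CFU-E (0.269) or KO Pre MegE (0.683). The macrophage call was lost without Het CFU-E (0.313), Het Pre MegE (0.2), KO CFU-E (0.0928), KO Pre CFU-E (0.26) or KO Pre MegE (0.431), without the filter (0.0556) or after quantile normalization (0.0729). The other lists had adjusted p from 0.178 to 0.872, and in 5 of them the median, the mean and the test differed in sign. A further test asked by 1 linear term whether the effect of each gfp allele grew or shrank in even steps over the 3 stages. It called 0 genes with limma (1029 at an unadjusted p under 0.05, smallest adjusted p 0.167). Zbtb46, the gene fixed to be read first, had a value of -0.39 per allele and stage (SE 0.0498, limma unadjusted p = 3.11e-05, adjusted p = 0.167). Rtp4 had -0.24 (limma unadjusted p = 2.03e-05, adjusted p = 0.167). Each genotype and stage had 1 array. Without the Het Pre MegE array 2 genes were called. A test for any difference among the 3 genotypes called 10 genes (493 at an unadjusted p under 0.05), which became 1 without Het CFU-E, Het Pre MegE, KO Pre CFU-E, KO Pre MegE or WT Pre CFU-E, 2 without WT CFU-E and 3 without WT Pre MegE.

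The KO minus WT differences were compared between cell types across 11560 genes, as a description with no p. Pearson's correlation was 0.42 between Pre MegE and Pre CFU-E, 0.20 between Pre CFU-E and CFU-E and 0.09 between Pre MegE and CFU-E. Spearman's values were 0.21, -0.07 and -0.09, and without the sex-linked genes Pearson's were 0.27, 0.05 and -0.05. Between DC and the 3 stages Pearson's correlation was -0.05, -0.04 and 0.09. These are the 6 pairs of cell types.

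CD4+ DC differed from the progenitors by a far larger set of genes. Cell type, organ (spleen against bone marrow) and sex by the sex-linked genes differ together here, so these differences cannot be assigned to cell identity alone. Cd83, a surface marker of mature DC, was 7.01 higher (SE 0.0517, 129-fold, adjusted p = 2.62e-14, 2 DC arrays against 9 progenitor arrays, higher in 2 of 2 genotypes). Its mean level in progenitors lay below the array medians, so this fold is best read as a lower bound. The other largest rises were the cytokine Il1b (6.94), the nuclease Dnase1l3 (6.93), H2-M2 (6.89), the MHC class II gene H2-Eb2 (6.87), the nuclear receptor Nr4a3 (6.76), the lectin receptor Klra17 (6.66) and P2ry10 (6.60). The largest falls were the Y-linked Eif2s3y (-6.81), the neutrophil granule protein Ngp (-6.33), carbonic anhydrase Car1 (-6.31), Ces2g (-5.91), Rhag (-5.76), Tspan32 (-5.70), the progenitor transcription factor Myb (-5.45) and Gstm5 (-5.40). Eif2s3y lay at 3.78 to 3.83 in DC, below the array medians (7.61 in WT and 7.64 in KO). Falls to levels below the median are best read as lower bounds, and so is their rank. Both DC arrays held Xist at 13.2 to 13.3 and Uty at 4.43 to 4.75, so sex went with tissue. Zbtb46 was 0.94 higher in DC (adjusted p = 0.0082), and without the WT DC array 0.38 higher and not called (adjusted p = 0.283). Over its alternatives the adjusted p ranged from 0.000269 to 0.283, with the call lost also with array weights (0.78, adjusted p = 0.0679) and without WT progenitors and the block (0.93, adjusted p = 0.0593).

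Whether DC and progenitor arrays were normalized together is not given in the sources used here, and their upper quartiles differ (641.43 and 604.76 in DC, 967.58 to 1009.3 in progenitors), which bears on every difference of this comparison. There were 10391 genes called of 11560, 2928 higher and 7463 lower in DC, and 5458 changed by at least 2-fold (1347 higher, 4111 lower). The median difference of all genes was -0.59 and went to -0.10 after quantile normalization, which split the calls into 4671 higher and 5512 lower. List tests compare a list with the other genes, so they are relative to that shift. MHC class II genes rose in 10 of 10 (median 5.37, adjusted p = 9.98e-10), with H2-Aa at 6.46 and Cd74 at 5.91, and classical DC core genes in 22 of 23, with 1 lower (median 5.21, adjusted p = 1.3e-15). CD4+ DC subset genes rose in 11 of 12 (median 3.44, adjusted p = 9.98e-10), with Clec4a4 at 6.39, the transcription factor Irf4 at 5.25, Cd4 at 5.06 and Sirpa at 4.14. The DC were sorted on CD11c, MHC class II, CD172, CD11b and CD4, so rises of the genes of these markers follow in part from the sort. Monocyte and macrophage genes rose in 14 of 14 (median 3.38, adjusted p = 9.98e-10), with Adgre1 at 6.11 and Csf1r at 5.15. DC maturation genes had 15 of 18 higher and 2 lower (median 2.58, adjusted p = 6.04e-09), with Cd86 at 6.27, Traf1 at 6.17 and Ccr7 at 5.26. Immediate early genes rose in 20 of 20 (median 2.25, adjusted p = 1.04e-12), with Nr4a1 at 5.50 and Egr2 at 4.95, and the CD8+ DC subset list in 8 of 8 (median 1.49, adjusted p = 9.46e-06), with Wdfy4 at 2.44.

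Cytokine receptors had 7 of 9 higher and 1 lower (median 2.25, adjusted p = 0.000514, adjusted p = 0.0775 with an estimated correlation), with Flt3 at 4.04 and Epor at -3.91. Interferon response genes had 12 of 17 higher and 2 lower (median 0.77, adjusted p = 3.88e-05, adjusted p = 0.209 with an estimated correlation), with Rsad2 at 3.47, and plasmacytoid DC genes 5 of 9 higher and 2 lower (median 0.27, adjusted p = 0.0129, adjusted p = 0.0957 with an estimated correlation), with Ccr9 at 3.65. Erythroid genes had 25 of 28 lower and 1 higher (median -3.79, adjusted p = 0.000175, adjusted p = 0.187 with an estimated correlation), with Aqp1 at -5.28 and Kel at -4.90. All 23 G2 and M phase genes fell (median -2.97, adjusted p = 0.000546, adjusted p = 0.591 with an estimated correlation), with Bub1 at -3.50, as did 25 of 25 DNA replication genes (median -2.69, adjusted p = 0.000138, adjusted p = 0.535 with an estimated correlation), with Rfc4 at -3.94, and 23 of 23 ribosome biogenesis genes (median -1.97, adjusted p = 0.000101), with Wdr12 at -3.36. Lists with single members far from 0 that did not pass were heme synthesis (10 of 12 lower and 2 higher, adjusted p = 0.136), iron handling (9 of 13 lower and 3 higher, 0.531), megakaryocyte (9 of 16 lower and 5 higher, 0.686), stem (13 of 20 lower and 4 higher, 0.622), granulocyte (12 of 19 lower and 7 higher, 0.963), mast cell (5 of 6 lower and 1 higher, 0.526) and cholesterol synthesis (11 of 18 lower and 5 higher, 0.834). Without the filter heme synthesis (0.00516) and stem genes (0.0483) passed as lower and NK cell genes as higher (0.00516). Plasmacytoid DC genes did not pass (0.071). B cell (0.308), T cell (0.531), NK cell (0.347) and sex-linked genes (0.332) did not pass either, and B cell genes had a median of -0.33 and a mean of 0.62, 1 of 3 lists, none of which passed, whose median, mean and test differed in sign. Of 25 lists 14 passed, 10 up and 4 down, and 8 held with an estimated correlation, those of classical DC core, MHC class II, CD4+ DC subset, CD8+ DC subset, monocyte and macrophage, DC maturation and immediate early genes, higher, and ribosome biogenesis, lower.

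Loss of Zbtb46 in CD4+ DC was read from the single KO and the single WT array, so these differences have no replicate check. The fixed lists of cell division and interferon response genes lay lower in the KO array, and the 2 largest positive differences were those of Csf3r and Vegfa. Csf3r, the receptor of granulocyte colony-stimulating factor, was at 9.55 in WT and 11.2 in KO, 3.24-fold higher, and the vascular growth factor Vegfa was 3.02-fold higher. Rtp4, an interferon-induced gene, was 2.67-fold lower in KO. Of 10554 genes 33 differed by at least 2-fold, 12 higher and 21 lower (15 and 17 after quantile normalization), and 267 by at least 1.5-fold, 80 higher and 187 lower.

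The largest positive KO minus WT differences were Csf3r (1.70), Vegfa (1.60), Pxdc1 (1.37), Snord14e (1.34), Tns1 (1.16, or 0.65 as the mean of its 6 probe sets), the calcium channel gene Cacna1e (1.16), Vps37b (1.14), the leukemia inhibitory factor receptor Lifr (1.12), Sema7a (1.05), the interleukin 12 subunit Il12b (1.03), the heat shock protein Hspb1 (1.01) and Klf10 (1.01). The largest negative ones were Zbtb46 (-1.65), Septin3 (-1.55), Rtp4 (-1.42), the interferon-induced genes Ifit3 (-1.35) and Oas2 (-1.27), Dapk1 (-1.30), Gfra2 (-1.28), Snord118 (-1.25), cyclin A2, Ccna2 (-1.17), Cd22 (-1.15), the lectin Mgl2 (-1.08) and Cd5l (-1.08).

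All 22 measured G2 and M phase genes were lower in the KO DC array, 19 of them by at least 0.5, and the list median of -0.72 lay at percentile 0 of random lists. Ccna2, Bub1 (-1.06), Kif11 (-1.05) and Ccnb2 (-0.91) were among them. Some erythroid transcripts were lower too, with 4 of 16 erythroid genes at least 0.5 lower (Slc4a1 at -0.94, Alas2 at -0.89, Car1 at -0.60 and Car2 at -0.59) and 8 of 16 above 0. Beta globin probe sets were at 13.2 and 13.1 in WT and 12.2 and 12.1 in KO. All 23 DNA replication genes were lower (median -0.53, percentile 0), with Mcm6 at -0.83 and Rrm2 at -0.82. Interferon response genes had 16 of 18 below 0 (median -0.45, percentile 0), with Ifit2 at -0.83 but Cxcl10 at 0.49. Monocyte and macrophage genes had 11 of 18 below 0 (median -0.37, percentile 0), with the complement genes C1qc at -0.80 and C1qb at -0.78 but Cd14 at 0.89 and Cx3cr1 at 0.62. Heme synthesis (median -0.24, percentile 0.62, Alas2 at -0.89) and the CD8+ DC subset (median -0.21, percentile 0.66) were low as well. Megakaryocyte genes (9 measured, median 0.23 or 0.09846 without the filter, percentile 99.96, Itgb3 at 0.61), cytokine receptors (9 measured, median 0.22, percentile 99.92) and DC maturation genes (16 measured, median 0.12, percentile 99.87, Cd80 at 0.43 and Cd86 at 0.41) were high.

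The medians of the classical DC core, CD4+ DC subset and MHC class II lists lay near 0, with members on both sides, while that of the CD8+ DC subset was low as given above. The classical DC core list of 24 genes had a median of 0.01 (percentile 80.93), with Nectin1 at 0.98 and Rab30 at -0.45, the CD4+ DC subset list -0.05 (percentile 39.76), with Mgl2 at -1.08, and MHC class II genes 0.00 (percentile 51.4). The other lists lay at percentiles from 10.29 for B cell genes (Cd22 at -1.15 and Ms4a1 at 0.97) to 96.65 for granulocyte genes. These were immediate early (40.56), stem (37.84), erythroid (19.85), iron handling (15.77), ribosome biogenesis (51.53), plasmacytoid DC (42.94), T cell (51.64) and cholesterol synthesis genes (95.93, with a median of 0.02 and a mean of -0.02). Mast cell and NK cell lists with 2 measured genes each and sex-linked genes with 1 were given no percentile.

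Given the spread between the progenitor arrays, 817 of 11560 genes were called between KO and WT DC, 256 higher and 561 lower, among them Vegfa (SE 0.0862, adjusted p = 0.000204), Csf3r (adjusted p = 0.000643), Rtp4 (adjusted p = 0.0106) and Zbtb46 (SE 0.392, adjusted p = 0.0398). These calls assume that the lone DC arrays vary like the progenitor arrays, which these data cannot check. For Zbtb46 that spread also holds the change of its KO minus WT difference over the stages (0.19, -0.44 and -1.37). The fit takes this difference to be alike at every stage, so the SE of Zbtb46 does not measure variation between arrays alone. By this test called monocyte and macrophage genes lay on both sides. Those of the G2 and M phase, DNA replication, interferon response, erythroid and heme synthesis lists were all lower. After quantile normalization the split was 730 higher and 885 lower. The count was 414 without the WT Pre CFU-E array, 477 without KO Pre MegE, 505 without Het CFU-E and 1235 without KO CFU-E. The Zbtb46 call was lost without the Het CFU-E, Het Pre MegE, KO Pre CFU-E or WT Pre CFU-E array and without the filter, with the difference unchanged at -1.65. With 1 KO effect shared by DC and progenitors, a different quantity, Zbtb46 was at -0.82 and was not called.

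**Figure D4:**
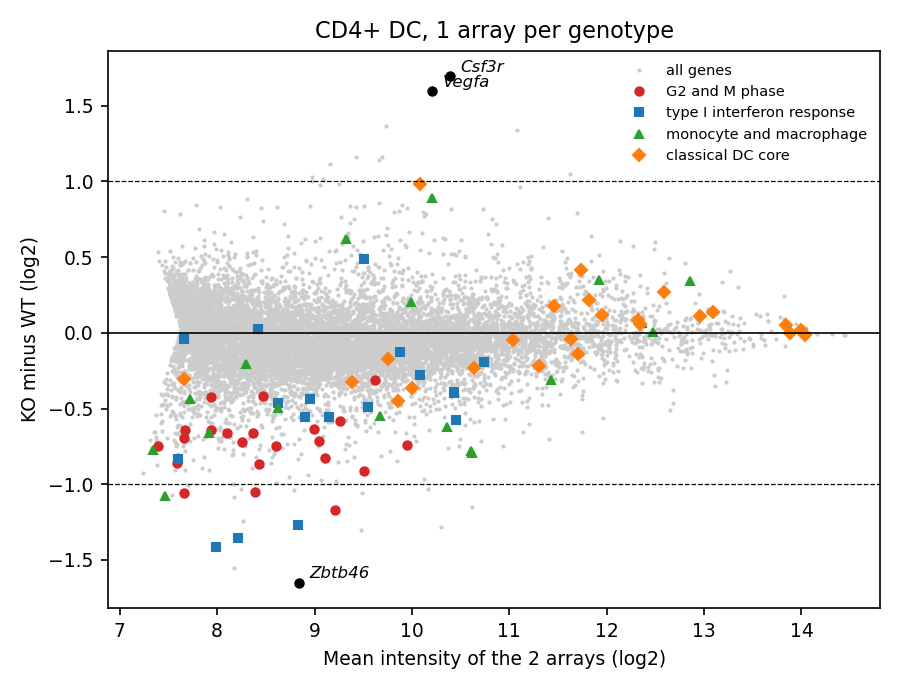
Difference in log2 intensity between the KO and the WT CD4+ DC array (y axis) against their mean log2 intensity (x axis), 1 point per gene, with G2 and M phase genes in red, interferon response genes in blue, monocyte and macrophage genes in green and classical DC core genes in orange, and dashed lines at 2-fold. G2 and M phase genes lie around -0.72 and classical DC core genes around 0.01, and Zbtb46 (-1.65), Csf3r (1.70) and Vegfa (1.60) are marked in black.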

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

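All of the tests of explanations in this part were chosen after the result was seen, as were the counts of other splits. No group held 4 or more arrays, so no array was tested for standing apart from its group.

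An interaction test in limma of whether the KO effect differs between CD4+ DC and progenitors called 528 genes, 180 with a higher and 348 with a lower value in DC (513 and 622 after quantile normalization). The DC arm is 1 array against 1, and the test gives it the spread of the progenitor arrays, an assumption these data cannot check. For Zbtb46 that spread includes the change of its KO minus WT difference over the stages, which the fit takes to be alike. Sex is confounded with genotype in the progenitor arm: the difference was 5.99 for Xist (adjusted p = 0.000237), which stems from the WT progenitors, so called genes need not reflect Zbtb46. Leaving out single arrays gave 201 (without WT Pre CFU-E), 235 (without KO Pre MegE), 282 (without WT CFU-E), 318 (without Het CFU-E), 347 (without KO Pre CFU-E) and 823 (without KO CFU-E). Among the genes with the largest DC differences, the KO effect in DC exceeded that in progenitors by 1.88 for Csf3r, 1.67 for Vegfa, 1.32 for Pxdc1, 1.19 for Vps37b, 1.10 for Klf10, 1.08 for Lifr, 1.08 for Sema7a, 1.07 for Tns1, 1.06 for Il12b, 1.03 for Cacna1e, 1.03 for Snord14e and 0.96 for Hspb1. It was lower in DC by -1.37 for Dapk1, -1.27 for Gfra2, -1.18 for Cd22, -1.17 for Ccna2, -1.17 for Oas2 and -1.12 for Snord118. All of these genes were picked for the largest differences of the same DC pair. Large values here follow in part from that choice and are no separate evidence of a difference between tissues. Snord118 was not called without the filter (adjusted p = 0.0545) or without KO Pre CFU-E (0.0506), KO Pre MegE (0.0823), WT CFU-E (0.0514) or WT Pre CFU-E (0.0883), the range being 0.0506 to 0.0883 where the call was lost. For Zbtb46 the difference of -1.11 was not called (adjusted p = 0.216), but it was with array weights (-1.28, adjusted p = 0.0457) and without KO CFU-E (-1.46, adjusted p = 0.021), with a range of 0.021 to 0.366. By list, 20 of 23 G2 and M phase, 16 of 25 DNA replication and 8 of 28 erythroid genes had a lower KO effect in DC, and 6 of 19 granulocyte genes a higher one.

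Probe sets outside the gene tests, with several gene symbols or not listed with a gene, were tested the same way. Of 3937 such probe sets, 1736 were called between Pre CFU-E and Pre MegE, 826 between CFU-E and Pre CFU-E and 2336 between CFU-E and Pre MegE. Between KO and WT progenitors 3 were called, all lower, and between KO and Het 2, both lower, each with several gene symbols.

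Granulocyte genes were lower in KO than in WT progenitors at each stage, with a list median of -0.23. RNA of neutrophil-lineage cells in the sorted samples is a candidate source: 9 of 9 markers of maturing neutrophils outside the list and the called genes lay below 0, with a median of -0.298, including the most abundant, Lcn2, at 11.652 in WT and 11.329 in KO, although the sorts selected lineage-negative cells. Fewer granulocyte-primed cells within the gates may give the same values, a biological explanation that was not tested. Sex of the mice cannot be told apart from genotype against WT: KO against Het, which share their sex, had a median of -0.05138, and Het against WT -0.1321. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05, and the list median was 0.2307 in size for the real split and at most 0.1937 for the other splits.

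Cell division genes were lower in the KO than in the WT CD4+ DC array. As the whole source, RNA of CFU-E like cells in the WT sample is argued against by their markers. The lost G2 and M phase signal needs a median share of 6.148% CFU-E RNA (2.662 to 9.686). The erythroid markers allow a median of 0.4229% (-5.242 to 4.226). These ranges overlap and come from a single pair of arrays, so a part of the loss from such cells is not excluded. Later erythroid cells, of which there is no array, stay open and were not tested: beta globin probe sets were at 13.2 and 13.1 in WT DC, 12.2 and 12.1 in KO DC and at most 11.981 in progenitors, with Slc4a1 (-0.94), Alas2 (-0.89), Car1 (-0.60) and Car2 (-0.59) also lower in KO, while 8 of 16 erythroid genes lay above 0. The gate on CD11c, MHC class II, CD11b and CD4 should remove such cells. The globin signal was nevertheless read in gated samples, so the gate does not decide this. Scaling does not account for it, since the G2 and M phase median was -0.678 after quantile normalization. RNA of red pulp macrophages stays open. Of their markers 14 of 18 lay below 0 (median -0.5869), but Adgre1 (0.07), Cd68 (0.01), Treml4 (0.08) and Spic (0.20) did not. In WT DC Cd68 was at 12.5 and Adgre1 at 12.3, and the gate on CD11c and CD4 should remove most such cells. There is no macrophage array to tell whether these cells hold division transcripts, so their markers cannot decide this. A lower share of dividing DC in KO may also give these values, and the single pair of arrays does not tell these apart.

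All 3 WT progenitor arrays held Xist (11.5 to 12.3) together with Y-linked genes, which were -0.3447 lower on average than in Het and KO arrays. RNA of male and female mice in the WT samples would give both, and is a candidate source. An exchange of arrays of 1 sex is excluded, since 3 arrays held both kinds of transcript. No biological explanation was tested.

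For the counts of called genes, the 10 splits of 6 arrays are again too few for a share under 0.05. The real split gave 7099 genes for Pre CFU-E against Pre MegE, 4712 for CFU-E against Pre CFU-E and 8202 for CFU-E against Pre MegE, with 0 as the highest of the others each time. KO against WT gave 15 with 2 as the highest other, Het against WT 4 with 0, and KO against Het 0 with 0, which all 10 splits equal. Relabeling within blocks allowed 36 arrangements, of which only the real one (1 of 36) reached 8389 genes for any stage, with 5420 as the highest other, so that chance arrangement of the stages is excluded at that share. For any genotype the real one gave 10 genes, with 8 as the highest other (1 of 36). This does not exclude chance differences between mice, since the arrays of a genotype may come from the same mice and the 3 WT arrays share the mixed sex-linked signal. That count was 1 without Het CFU-E, Het Pre MegE, KO Pre CFU-E, KO Pre MegE or WT Pre CFU-E, 2 without WT CFU-E and 3 without WT Pre MegE.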

How the results depend on the processing

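Array weights estimated gene by gene, the alternatives that left out the WT arrays, 1 stage or the sex-linked list, and the alternatives for single genes of the DC pair with the progenitors' spread and of the difference of the KO effect were chosen after the data were seen. No paired analysis was possible by mouse because the labels do not pair arrays by mouse, and the fits compare within genotype and stage blocks. Leaving out a DC array gives the DC pair no value. Of 350 values of 27 counts and correlations, 268 stayed within 1.5-fold or 0.1, 81 moved and 1 of at least 0.1 in size reversed. Smaller correlations also changed sign, that of Pre MegE with CFU-E as given below and that of Pre MegE with DC to 0.007613 without the filter. Of 3543 values for 206 named results, 3292 kept direction and call, 223 lost the call, 19 gained it, 2 moved and 7 reversed, the reversals all for Zbtb46 in Het against WT. Of 2071 list medians, 1961 were the same, 78 lost the call, 28 gained it and 4 moved, which were, in the DC pair, erythroid (-0.178) and megakaryocyte genes (0.09846) without the filter and heme synthesis (-0.1629) and iron handling genes (-0.03875) after quantile normalization. Among named genes of the stage comparisons only Zbtb46 lost a call. Where no cause is given below, the cause was not tested.

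With array weights, 46 genes were called for KO against WT, 21 for Het against WT, 2 for KO against Het, 33 for any genotype, 3 for the trend, 1558 for KO against WT DC with the progenitors' spread and 1152 for the difference of the KO effect between DC and progenitors, where the lone DC arrays keep a weight of 1 so that only progenitor arrays are reweighted. After quantile normalization the latter 2 counts were 1615 and 1135. With 1 KO effect shared by DC and progenitors, limma called 0 genes, but that effect is a different quantity from KO minus WT in DC. Without the filter, which tests more genes, 7 were called for KO against WT, 1 for Het against WT, 1 for any genotype and 1 for the trend. Without the CFU-E, Pre CFU-E or Pre MegE arrays, which leaves fewer arrays, the count was 2, 1 and 1 for KO against WT and 1, 1 and 2 for Het against WT. Het against WT gave 1 with only the 2 genotypes compared and 0 by limma without the sex-linked list. CFU-E against Pre CFU-E gave 3134 genes from Het and KO arrays only, 3111 of them shared. In the DC pair 267 genes passed 1.5-fold and 3 passed 3-fold.

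With an estimated correlation, lists past the threshold were 4 for Pre CFU-E against Pre MegE, 3 for CFU-E against Pre CFU-E, 6 for CFU-E against Pre MegE, 8 for DC against progenitors, 1 for KO against WT and 0 by camera for Het against WT and for KO against Het. The KO minus WT correlation between Pre CFU-E and CFU-E was -0.07017 by Spearman, a reversal, and 0.04898 without sex-linked genes. Between Pre MegE and CFU-E these were -0.09456 and -0.04686, and between Pre MegE and Pre CFU-E 0.2147 and 0.2706, with 0.2186 without the filter. That of KO with Het was 0.6189 without Pre CFU-E arrays and 0.6709 without sex-linked genes. The Zbtb46 difference of Het from WT reversed to -0.0975 with array weights, -0.0487 without Pre CFU-E arrays and -0.0465 without Pre MegE arrays.

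Leaving out 1 array gave 1 (WT Pre CFU-E) to 26 genes (Het Pre CFU-E) for KO against WT, 1 (Het CFU-E and others) to 5 (KO CFU-E) for Het against WT, 0 (Het CFU-E) to 1 (Het Pre CFU-E) for KO against Het, 1 (KO Pre MegE and others) to 15 (Het Pre CFU-E) for any genotype and 0 (Het CFU-E) to 2 (Het Pre MegE) for the trend. For KO against WT DC with the progenitors' spread the range was 414 (WT Pre CFU-E) to 1235 (KO CFU-E), and for the difference of the KO effect 201 (WT Pre CFU-E) to 823 (KO CFU-E). Lists past the threshold ranged from 3 (WT CFU-E) to 6 (Het Pre MegE) for KO against WT, 1 (Het CFU-E or Het Pre CFU-E) to 3 for Het against WT and 0 (KO Pre CFU-E) to 3 for KO against Het. The Zbtb46 difference of Het from WT ranged from -0.1949 (WT Pre MegE) to 0.2968 (WT CFU-E), and was -0.0488 without Het CFU-E, -0.0237 without Het Pre CFU-E and -0.0388 without WT Pre CFU-E. The total counts of the stage comparisons and of DC against progenitors stayed within 1.5-fold whichever array was left out, but the 2004 higher genes of CFU-E against Pre CFU-E became 1322 without WT Pre CFU-E. Array signal limits what can be seen: with the filter, genes at or above the array median on fewer than 2 arrays of a limma fit were not tested.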

Other observations

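Apart from the test of the genes near Zbtb46, which was planned, the genes in this part were chosen after their values were seen, and no explanation is offered for them. Single chaperone genes were read in the KO CD4+ DC array, with Bag3 at 0.96, Hspa1l at 0.83, Dnaja1 at 0.60, Hsph1 at 0.46, Hsp90aa1 at 0.41 and Hspa1a at 0.25 relative to WT. Of these, Bag3, Hspa1l, Dnaja1 and Hsp90aa1 passed the test with the progenitors' spread (adjusted p = 0.00291, 0.00101, 0.00557 and 0.0430) and Hsph1 and Hspa1a did not (0.0688 and 0.355). The fixed immediate early and heat shock list showed no such direction, with 12 of 20 genes below 0 and a median of -0.01 at percentile 40.56. The oxidative stress regulator Nfe2l2 was at 0.76, with Srxn1 at 0.76, Slc7a11 at 0.54 and Txnrd1 at 0.42, but other genes of that response went the other way, Gclm at -0.42 and Hmox1 at -0.31. Hes1, a target of Notch signalling, was at 0.77 and the hypoxia-responsive Ndrg1 at 0.66. The growth factor Igf1 was at -1.04, and macrophage genes with lower values included Mrc1 (-0.98), Axl (-0.84), Fcna (-0.82) and the iron exporter Slc40a1 (-0.76). These are differences between 2 arrays, with no replicate check.

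Values of single granulocyte genes were read in Het and KO progenitors, and no difference between kinds of granule genes was tested. Relative to WT, Elane was at -0.42 in Het and -0.43 in KO, Prtn3 at -0.35 and -0.33, Ctsg at -0.39 and -0.30, and Mpo at -0.29 and -0.23. S100a8 was at -0.04 in Het and -0.33 in KO, Ltf at -0.04 and -0.26, Lyz2 at 0.02 and -0.28, and Camp at 0.00 and -0.23. None of these KO minus Het differences passed limma's test (adjusted p = 0.957 for Ltf and 1 for the others named). Eosinophil markers, chosen after the values were seen and including the called Epx and Prg2, had 6 of 6 below 0 in KO against WT (median -0.49). Among them were Ear6 (-0.65), Prg3 (-0.38) and Alox15 (-0.23), while Siglecf was at -0.01.

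Genes within 5 Mb of Zbtb46 were read for differences linked to the targeted allele. Of 42 measured in progenitors, limma called 0 between KO and WT (1 at an unadjusted p under 0.05), and their shift against other genes gave a camera p of 0.73. In the DC pair 0 of 41 differed by 2-fold, with a mean absolute difference of 0.156 against 0.173 for the other genes.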
